A study of Mus musculus with 4 samples.

How the data were processed

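Mouse embryonic stem cells, WT and without Dgcr8 or Dicer, were grown with leukaemia inhibitory factor and serum, per the labels' protocols. RNA was extracted with Trizol, polyadenylated RNA was made into stranded libraries, and small RNA libraries were made from WT total RNA. The submitters' processing notes name Bowtie, with no version, and the mouse build mm9. The counting tool, the annotation, the use of strand and any trimming are not given in the sources used here. The mRNA table holds whole-number counts per RefSeq transcript entry as the authors deposited them, with 1 column per library, and the small RNA table holds deposited counts per mature miRNA, with no header line. Units were read from the values, which are whole numbers with a different total in each library. Columns were matched to groups by their names, and the small RNA column by being the only small RNA sample.

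The mRNA table has 13815 rows, 13196 with a coding and 619 with a noncoding RefSeq entry. Empty cells (252 in WT, 221 in the Dgcr8 knockout and 138 in the Dicer knockout) were read as 0. Every row reaches at least 10 counts in 1 library, so genes below that in all 3 were not analysed here. Spreadsheet dates stand in place of 21 symbols, and these rows were named through their RefSeq entry. For names and neighbours only, rows were matched to RefSeq genes of the assembly GRCm38.p6, 13641 by accession, 131 by symbol and 31 by synonym, and 12 stayed unmatched; no coordinates are given because the builds differ. Counts from 2 to 9 were even for 69.6% of genes in WT, 74.8% in the Dgcr8 knockout and 69.7% in the Dicer knockout, as when both mates of a pair are counted; the counting intervals are then too narrow. There were 28 rows in 12 sets with identical counts in all 3 libraries and 50 or more in 1. Some sets are near-identical copies (Duxbl2 and Duxbl3) whose reads were counted for each, and others are unrelated genes that can match by chance.

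Counts were scaled to CPM over the table. Log2 ratios were taken on log2(CPM + 1), which understates the change of low genes. Genes at 1 CPM or more in at least 1 of the 2 libraries entered, and a gene was called higher or lower at 2-fold or more. With 1 library per group there was no test. Ratios of named genes are ratios of CPM with an exact conditional binomial 95% interval for counts. Where 1 library was at 0, the fold is a lower bound against 3 counts in that library. The 24 gene lists were described by the median log2 ratio, its percentile among 10000 random lists matched in 20 bins of mean expression, and the number of members at 2-fold; a median was called high or low at a percentile of 97.5 or more, or 2.5 or less, and lists with fewer than 3 tested members got no median. The lists of miRNA biogenesis genes, protein-coding hosts and Microprocessor substrates hold Dgcr8, and the first of these also Dicer1. Some lists share members, such as those of G1/S genes, let-7 targets and AAGUGC-seed targets, so their medians are not independent. Members were matched by the symbol in the table or the current symbol of its entry. The ratios of the knockouts to the shared WT library were set beside 20 simulated sets of 3 unchanged libraries per assumed coefficient of variation.

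MiRNA shares are reads over all reads of the small RNA table, with exact Clopper-Pearson 95% intervals. PCR reads are not independent molecules, so all intervals and floors cover counting error only. A miRNA made by several loci was counted in each cluster it belongs to. Hosts were noncoding genes, or listed protein-coding genes, with a miRNA gene inside their GRCm38.p6 span or within 2 kb of it, and their mature level is the sum over those miRNAs. The planned use of positions needed a reference of the authors' build; only which genes neighbour each other was used. The model of Mir17hg in the authors' annotation is not given in the sources used here.

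Named genes followed a rule fixed beforehand. It takes the targeted genes, the 6 highest and 6 lowest log2 ratios of each pair among genes at 5 CPM or more in the higher library (without unnamed predicted loci and olfactory or vomeronasal receptors), up to 4 members of each list with the largest ratios and any needed to show both directions, the 5 genes with the largest smaller change in each direction for the overlap, all noncoding hosts above the floor, the 10 most abundant miRNAs and the members of 4 miRNA clusters. Some genes that this rule takes are not reported here. Groups, tests, lists and most other settings were fixed before the data were examined. The other settings changed the pseudocount (0.1 and 5), the floor (none and 5 CPM), the scaling (median-ratio size factors, and TMM by edgeR 4.0.16 in R 4.3.3), the size rule (1.5-fold and 4-fold) and the treatment of rows sharing a symbol, arms and multi-locus miRNAs. Settings without ribosomal protein genes, with 1 row of each identical set, without chromosomes 1 and 8, with noncoding hosts only and with miRNA genes inside the host span were chosen after seeing the data.

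The method was tested on simulated counts drawn from the means and totals of each pair, with 200 changed genes. The draws were Poisson, with no variation between cultures or libraries. The shares called and the coverage below therefore hold for counting error only and do not give the error rate of the real comparisons. For the Dgcr8 knockout against WT (12911 genes), 98% of 4-fold, 30% of 2-fold and 2% of 1.5-fold changes were called, and 0.0158% of unchanged genes. For the Dicer knockout against WT (13060 genes) the shares were 100%, 36%, 0% and 0.0390%, and for the Dgcr8 against the Dicer knockout (12787 genes) 98%, 40%, 2% and 0%. All 8-fold changes were called in each pair. The intervals covered the true ratio for 94%, 97.5% and 94.5% of the changed genes in these pairs. A list changed by 1.5-fold came out at the percentile 100 in each pair. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.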

Results

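Poly(A)-selected RNA was sequenced from mouse embryonic stem cells of the V6.5 line (WT) and from cells without Dgcr8 or without Dicer, and small RNA was sequenced from WT cells. DGCR8 is the RNA-binding partner of Drosha in Microprocessor, which releases the hairpin from a primary miRNA transcript in the nucleus. Dicer cuts the released hairpin into the mature miRNA duplex in the cytoplasm. Each of the 4 groups has 1 library, so no difference below has a replicate check, no test between conditions was run, and no p-value is given. Ratios compare the libraries named, and their 95% intervals cover counting error only. The intervals are too narrow even for that if both mates of a pair were counted, as the mostly even low counts leave possible. The mRNA table lists 13815 genes and holds 9931625 counts for WT, 11123498 for the Dgcr8 knockout and 12309100 for the Dicer knockout. Counts were scaled to CPM, the same total in each library, and 1 CPM is 9.93 counts in WT, 11.12 in the Dgcr8 knockout and 12.31 in the Dicer knockout. The small RNA table lists 707 mature miRNAs with 2594949 reads in all.

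The targeted genes were lower in the libraries labelled as their knockouts, and neither was at 0. Dgcr8 had 52.7 CPM (523 counts) in WT, 20.9 CPM (232 counts) in the Dgcr8 knockout and 84.7 CPM (1043 counts) in the Dicer knockout. Its level in the Dgcr8 knockout was 2.52-fold lower than in WT (95% interval 2.16 to 2.96). Dicer1 had 79.9 CPM (794 counts) in WT, 128 CPM (1419 counts) in the Dgcr8 knockout and 20.1 CPM (247 counts) in the Dicer knockout, which was 3.98-fold lower than in WT (3.45 to 4.61). The knockout alleles are not described in the labels, so counts from parts of the genes left in place cannot be separated from full-length transcripts. Each gene was higher than in WT where the other was targeted, Dgcr8 by 1.61-fold (1.45 to 1.79) and Dicer1 by 1.60-fold (1.46 to 1.74).

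The comparison of the Dgcr8 knockout with WT asks which transcripts differ when the first processing step is lost. With 1 library of each, differences between the cell lines or cultures cannot be separated from the genotype. Mid1, a microtubule-associated ubiquitin ligase, had 3 counts in WT and 3961 in the knockout, a ratio of 1179 (403 to 5719). Casq2, which encodes a cardiac calsequestrin, had an empty cell in WT, read as 0, and 521 counts in the knockout. It was at least 155-fold higher against a floor of 3 counts in the WT library. Every mRNA count given as 0 is such an empty cell. Hoxa10 was also at 0 in WT and had 302 counts in the knockout, at least 89.9-fold higher. The transcription factor gene Zic2 was 40.2-fold higher (25.3 to 68.2). Lefty1, an antagonist of Nodal signalling, had 46.8 CPM in WT and 1312 CPM in the knockout, 28.0-fold higher (25.5 to 30.8). At the other end, Pla2g1b was 126-fold lower (57.6 to 345), Myl4 52.9-fold lower (20.3 to 196), Fgfr3 51.1-fold lower (23.2 to 141), Crabp1 31.2-fold lower (19.5 to 53.03) and the basement membrane gene Lama1 15.9-fold lower (12.27 to 21.0). Cyp11a1 had 189 counts in WT and 0 in the knockout, at least 70.6-fold lower. Of 13223 genes at 1 CPM or more in either library, 1891 were at least 2-fold higher and 1060 at least 2-fold lower on the log2(CPM + 1) scale. The median log2 ratio of all these genes was 0.11. Median-ratio scaling moved that median by -0.14 and gave 1540 higher and 1369 lower genes, so that genes higher made up 52.9% of the calls instead of 64.1%. TMM scaling moved it by -0.11.

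Among the gene lists fixed before the data were examined, the reported targets of AAGUGC-seed and miR-17~92 miRNAs had a median log2 ratio of 0.88 in the Dgcr8 knockout, at the percentile 100 of 10000 random lists matched on expression. Of its 31 members tested, 14 were at least 2-fold higher and 0 lower. The members with the largest ratios were Lefty1 (log2 ratio 4.78), the Hippo pathway kinase gene Lats2 (21 counts in WT and 542 in the knockout), Nr2f2 (2.72) and Dazap2 (2.55), and Ccng2 was at -0.61. The G1/S cell cycle list had a median of 0.72 (percentile 99.97). In it the cyclin genes Ccnd2 and Ccnd1 were at 3.96 and 2.44, the cell cycle inhibitor gene Cdkn2a at 2.54 and the inhibitor gene Cdkn1c at -3.25. The let-7 target list had a median of 0.56 (percentile 99.52), with Hmga2 at 2.83 and Dusp9 at -3.11. The list of TGF-beta, YAP and mesenchymal genes had a median of 0.94 (percentile 100), with Cdh2 (N-cadherin) at 3.05, the intermediate filament gene Vim at 2.85 and Tgfb1 at -1.45. Of 20 interferon and double-stranded RNA response genes, 12 were at least 2-fold higher and 0 lower, with a median of 1.26 (percentile 100; 1.51 with genes at 0 set at their bound). Oasl2 was at 3.07, Oas1a at 2.84, Ifitm3 at 2.73 and Irf9 at 2.45, while Bst2 was at -0.92.

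The stem cell and lineage lists of the Dgcr8 knockout were mixed. The core and naive pluripotency list had a median of 0.17 (percentile 88.7), with 6 members at least 2-fold higher and 5 lower. Klf2 was at 3.56, and Klf4, Tbx3 and Tdgf1 were at -2.05, -1.67 and -1.65. The neural ectoderm list had a median of 1.32 (percentile 99.83), with Nefm at 2.79 and Pax6 at 2.53, each from 2 counts in WT, and Nefl at 1.88. The trophectoderm list had a median of 1.25 (percentile 99.89), with Tead4 at 2.05 and Krt18 at 1.59. The endoderm list was low, with a median of -0.90 (percentile 0.11), Hnf4a at 99 counts in WT and 0 in the knockout and Gata4 at 1.80. The germline list was low too, with a median of -0.85 (percentile 0.01), Stra8 at -3.20 and Tex11 at 0.92. The list of feeder fibroblast and stromal genes, another cell type such a culture can hold, had a median of -0.01 (percentile 40.9), with Vim at 2.85 and the collagen gene Col1a1 at -2.81. The miRNA biogenesis and RISC list had a median of 0.44 (percentile 98.91; 93.75 with a pseudocount of 5), with Ago1 at 2.28, Ago2 and Tnrc6a at 2.06 and the let-7 regulator gene Lin28a at -2.30. Medians inside the central 95% of random lists were found for primed epiblast genes (0.53), mesoderm (-0.62), cleavage and polyadenylation factors with Isy1 (0.13), p53 targets (0.08), DNA methylation (0.25), imprinted genes (0.10), sex chromosome markers (-0.87), reported mRNA substrates of Microprocessor (-0.62) and housekeeping genes (-0.07). Only 1 member of the 2-cell-like list, Eif1a, passed the floor in this pair.

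The comparison of the Dicer knockout with WT asks the same of the second processing step, and cell line and culture cannot be separated from genotype here either. Mid1 was higher here as well, 276-fold (94.2 to 1340), and Casq2, at 768 counts, was at least 207-fold higher. Prdm1, which encodes the transcriptional repressor BLIMP1, was 120-fold higher (46.7 to 443) and the fatty acid transporter gene Slc27a2 119-fold higher (46.3 to 439). Duxbl2 and Duxbl3 were both 102-fold higher (39.5 to 375), with the same counts in each of the 3 libraries, so reads of near-identical copies cannot be told apart there. The genes with the lowest ratios were Tex13, 214-fold lower (72.8 to 1041), Pou2f3, 200-fold lower (55.0 to 1660), the neuronal growth gene Gap43, 184-fold lower (50.5 to 1527), the meiosis gene Stra8, 50.1-fold lower (34.0 to 77.0), Kdelr3, 49.0-fold lower (31.5 to 80.7), and Crabp1, 38.8-fold lower (23.7 to 68.4). Of 13403 genes, 2144 were at least 2-fold higher and 1300 at least 2-fold lower. The median log2 ratio was 0.10, and median-ratio and TMM scaling both moved it by -0.10. They gave 1917 higher and 1533 lower genes, and 1919 and 1531, so that genes higher made up 55.6% of the calls under either instead of 62.3%.

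The reported targets of AAGUGC-seed and miR-17~92 miRNAs had a median of 0.92 in the Dicer knockout (percentile 100), with 14 of 31 members at least 2-fold higher and 1 lower. Lefty1 was at 4.80, Lats2 at 3.81, Dazap2 at 2.75, Casp2 at 2.08 and Ccng2 at -1.01. The let-7 target list had a median of 0.82 (percentile 99.98), with Ccnd2 at 4.82, Lin28b at 2.23, Mycn at 2.17 and Dusp9 at -2.84. The G1/S list had a median of 0.66 (percentile 99.9) and included Ccnd3 at -2.06. The TGF-beta, YAP and mesenchymal list had a median of 1.35 (percentile 100), with Cdh2 at 4.64, Thbs1 at 4.29 and Inhbb at -2.93. The miRNA biogenesis and RISC list had a median of 0.48 (percentile 99.2), with Ago1 at 2.40 and Tnrc6a at 2.20. DNA methylation genes had a median of 0.63 (percentile 99.43), with Mbd2 at 2.02 and Dnmt3a at 1.11 beside Dnmt3l at -1.74. The interferon list had a median of 0.41 (percentile 91.06), with Ifitm1 at 4.11 and Bst2 at -1.41.

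In the Dicer knockout the 2-cell-like list had a median of 3.003 (percentile 100), and 8 of its 9 tested members were at least 2-fold higher. Apart from Eif1a, the tested members were below 1 CPM in WT and entered only through the Dicer knockout library. They could therefore only come out higher there. Without a floor the median was 2.99 (percentile 100), though every row of the mRNA table reaches at least 10 counts in 1 library. Zscan4c had 7 counts in WT and 326 in the Dicer knockout, and Zscan4f, Zscan4d and Zscan4a were at 3.87, 3.84 and 3.56. The Zscan4 genes are near-identical copies, so their separate counts are uncertain and they are not independent members of the list. The primed epiblast list had a median of 1.499 (percentile 99.97), with Cdh2 at 4.64, Zic2 at 4.51, Otx2 at 3.44 and Pou3f1 at -0.19. The neural ectoderm list had a median of 1.34 (percentile 99.88; 1.67 with genes at 0 set at their bound), with Pax6 at 3.77, Nefm at 2.96 and the neurogenic factor gene Neurod1 at 2.93. The trophectoderm median was 1.17 (percentile 99.55) and the endoderm median -0.75 (percentile 0.69); with a floor of 5 CPM both lay inside the central 95% of random lists, at 92.3 and 6.57. The germline list had a median of -0.58 (percentile 0.68), with the X-linked genes Rhox6 and Rhox9 at 4.23 and 4.03 and Stra8 at -5.10. The imprinted list had a median of -0.30 (percentile 1.95; 8.58 without a floor), with Plagl1 at 3.26, Peg3 at 3.19, Rian at -3.50 and Meg3 at -2.91. The core and naive pluripotency list had a median of 0.15 (percentile 87.2), with Klf2 at 3.09, Tbx3 at -3.57, Klf4 at -2.47 and Zfp42 at -2.35. Feeder and stromal genes had a median of 0.04 (percentile 48.0), with Vim at 2.12 and the surface antigen gene Thy1 at -3.02. The other medians stayed inside the random range: mesoderm (-0.41), cleavage and polyadenylation factors with Isy1 (0.01), p53 targets (0.33), sex chromosome markers (-1.17), reported Microprocessor substrates (0.16) and housekeeping genes (0.05).

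Many genes stood apart from WT in the same direction in both knockouts. The genes with the largest smaller ratio included Mid1, Casq2, Lefty1 and Zic2 on the higher side, and Crabp1, Fgfr3, Cyp11a1, Gap43 and the selenoprotein gene Gpx3 on the lower side. Lefty1 had 465 counts in WT, 14589 in the Dgcr8 knockout and 16368 in the Dicer knockout, and Gpx3 had 329, 17 and 21. Of 13054 genes tested in both pairs, 1275 were at least 2-fold higher in both and 699 at least 2-fold lower in both, where independent lists of these sizes would share 268 and 106. The log2 ratios had a Pearson r of 0.83, a Spearman rho of 0.81 and a covariance of 0.74 across genes, which are not replicates. Both ratios use the same WT library, which gives agreement without any effect. Unchanged libraries simulated against a shared WT library with an assumed biological coefficient of variation of 0.2 gave an r of 0.51, a covariance of 0.09, and 20.15 and 7.65 shared genes. With an assumed coefficient of 0.4 they gave an r of 0.50, a covariance of 0.31, and 491 and 350 shared genes. Part of the excess over these values may come from the shared WT library, which cannot be split.

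**Figure D1:**
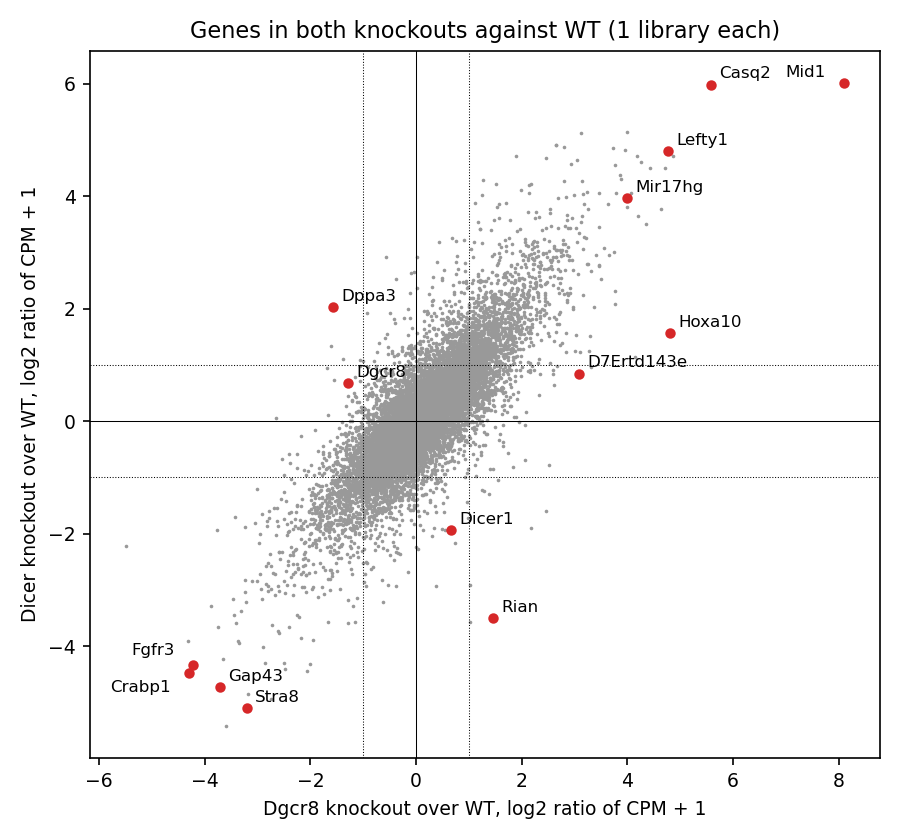
Log2 ratio of CPM + 1 of each gene in the Dgcr8 knockout over WT (horizontal axis) and the Dicer knockout over WT (vertical axis), 1 point per gene and 1 library per group; dotted lines mark 2-fold and red points are named. Most genes lie along the diagonal (Pearson r 0.83), while Rian lies at 1.45 and -3.50.

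The comparison of the knockouts with each other does not use the WT library. Cultures and genotypes cannot be separated in it, with 1 library of each. Transcripts of the imprinted Dlk1-Dio3 locus were among the highest in the Dgcr8 knockout. Rian had 1287 counts there and 34 in the Dicer knockout, a ratio of 41.9 (29.8 to 60.8), Meg3 had 242 and 6, a ratio of 44.6 (20.2 to 123), and Mirg had 173 and 0, at least 63.8-fold higher. Kbtbd11 was 94.6-fold higher (36.6 to 349), the ferlin family gene Myof 20.3-fold higher (15.5 to 27.0) and the activin subunit gene Inhbb 10.4-fold higher (8.95 to 12.2). On the lower side, Zscan4a and Zscan4b were at 0 in the Dgcr8 knockout and at least 70.8-fold and 44.0-fold lower than in the Dicer knockout. Insm1, a neuroendocrine transcription factor gene, was 103-fold lower (28.3 to 860), Zscan4c 49.1-fold lower (22.3 to 135), Zscan4d 45.2-fold lower (17.4 to 167) and Zscan4f 38.0-fold lower (18.2 to 95.2). Of 12986 genes, 539 were at least 2-fold higher in the Dgcr8 knockout and 656 at least 2-fold lower, with a median log2 ratio of 0.00.

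Of the gene lists, the noncoding miRNA hosts stood highest in the Dgcr8 knockout relative to the Dicer knockout, with a median log2 ratio of 1.20 (percentile 100), 8 of 13 members at least 2-fold higher and 1 lower. Of those higher, Rian, Mirg, Meg3 and 6430411K18Rik come from the same Dlk1-Dio3 locus and are not independent. The 16 noncoding hosts outside that locus, a set chosen after the data were seen, had a median of 0.19 (percentile 87.16). The 12 of these with a listed mature miRNA had 0.95 (percentile 100). Among them, Dleu2, C430049B03Rik, E130102H24Rik and 2610203C20Rik reached 1 CPM in the Dgcr8 but not the Dicer knockout. They could only come out higher in the Dgcr8 knockout, and Ftx, with the reverse, only lower. The interferon list was higher in the Dgcr8 knockout (median 0.46, percentile 99.99), with Oasl1 at 1.53 and Ifitm1 at -2.12, and so was the pluripotency list (0.17, percentile 98.43), with Zfp42 at 2.01 and Dppa3 at -3.61. Lists lower in the Dgcr8 knockout were 2-cell-like genes (-3.67, percentile 0; -3.93 with genes at 0 set at their bound), primed epiblast genes (-1.05, percentile 0), reported Microprocessor substrates (-0.75, percentile 0.86; 4 members tested, of which only Dgcr8 itself, at -1.97, was at least 2-fold lower), germline genes (-0.61, percentile 0.29), neural ectoderm (-0.51, percentile 0.5, but 15.64 with a floor of 5 CPM), let-7 targets (-0.28, percentile 0.03) and p53 targets (-0.27, percentile 0.05). Among their members, the neural gene Neurod1 was at -2.91, the germline gene Rhox9 at -2.78 and the epiblast genes Sox4 and Dnmt3a at -1.69 and -1.05. Apart from Eif1a, the tested 2-cell-like genes passed the floor only through the Dicer knockout library and could only come out lower in the Dgcr8 knockout. Without a floor their list had a median of -3.66 (percentile 0). Of 21 p53 targets, 0 were at least 2-fold higher and 0 lower, and of 20 let-7 targets 1 was higher and 1 lower. The reported AAGUGC-seed targets had a median of 0.13 (percentile 93.92), with Lefty2 at 1.22 and Ei24 at -0.72. Medians inside the random range were also found for G1/S genes (0.02), TGF-beta, YAP and mesenchymal genes (0.18), miRNA biogenesis and RISC genes (-0.02), DNA methylation (-0.04), imprinted genes (-0.16), trophectoderm (-0.13), endoderm (-0.22), mesoderm (0.38), feeder and stromal genes (0.02), cleavage and polyadenylation factors with Isy1 (0.13), protein-coding miRNA hosts (0.09) and housekeeping genes (-0.14). Sex chromosome markers had 2 members above the floor and no median.

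**Figure D2:**
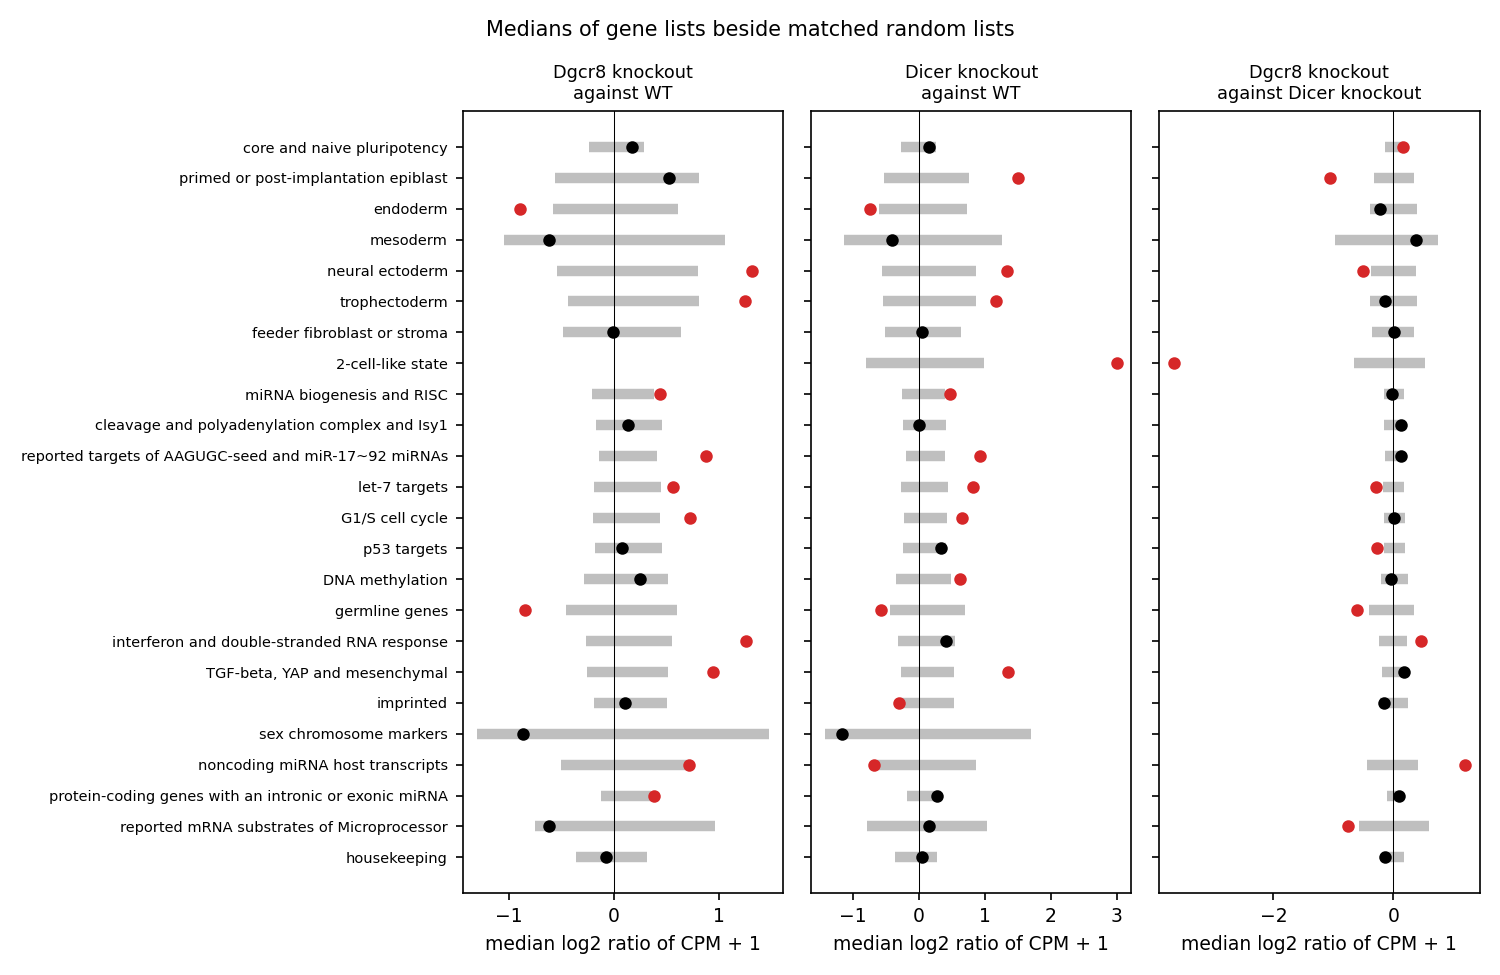
Median log2 ratio of CPM + 1 of each gene list (points) in the 3 pairs of libraries, with the central 95% of medians of 10000 expression-matched random lists (grey bars); red points lie outside that range. The reported AAGUGC-seed and miR-17~92 targets lie at 0.88 and 0.92 against WT and at 0.13 between the knockouts.

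The libraries also differed by chromosome, a comparison chosen after the data were seen, over 10434 genes at 5 CPM or more on average. Genes of chromosome 8 had a median log2 ratio of 0.19 in the Dgcr8 knockout against WT, -0.29 in the Dicer knockout against WT and 0.48 between the Dgcr8 and Dicer knockouts (591 genes). Genes of chromosome 1 had medians of 0.19, -0.07 and 0.30 (566 genes). The other autosomes had medians from -0.05 to 0.42 in the Dgcr8 knockout against WT, from -0.09 to 0.35 in the Dicer knockout against WT and from -0.12 to 0.06 between the knockouts, where the X chromosome had -0.14. Against WT, chromosome 8 in the Dicer knockout lay outside these ranges, while chromosome 8 in the Dgcr8 knockout lay inside them. The median of chromosome 1 lay inside them in both knockouts but hides opposite shifts in the Dgcr8 knockout: with its genes in 10 equal parts, parts 1 to 4 had medians from -0.43 to -0.15 in the Dgcr8 knockout against WT and parts 6 to 10 from 0.34 to 0.61. In the Dicer knockout against WT the same parts had medians from -0.37 to -0.01 and from -0.11 to 0.04. Medians below 0 in parts 1 to 4 were thus found in both knockouts. Between the knockouts the shift of chromosome 1 was in the distal part. Of the genes named above, Kbtbd11, Zfp42, Klf2 and Bst2 lie on chromosome 8, and Inhbb, Lefty1 and Lefty2 in the distal part of chromosome 1. Without chromosomes 1 and 8, 412 genes were at least 2-fold higher in the Dgcr8 than in the Dicer knockout and 612 at least 2-fold lower.

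**Figure D3:**
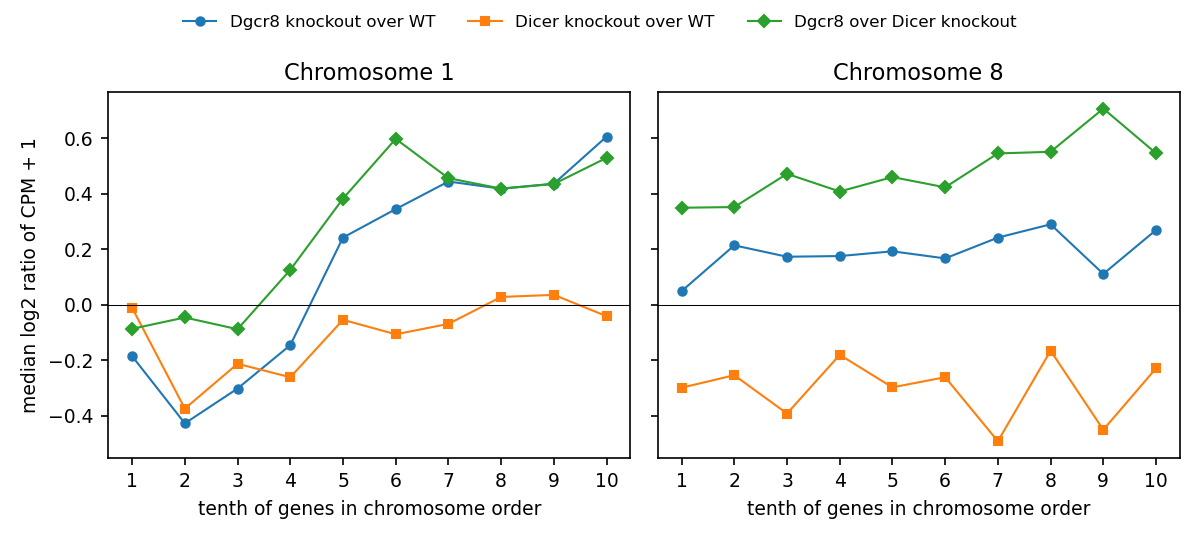
Median log2 ratio of CPM + 1 (vertical axis) of the genes of chromosomes 1 and 8 in 10 equal parts in chromosome order (horizontal axis), for the 3 pairs of libraries. On chromosome 1 the ratio of the Dgcr8 to the Dicer knockout is -0.09 in the first part and 0.53 in the last, and on chromosome 8 it lies between 0.35 and 0.71.

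The primary transcript of miR-17~92 was high in both knockouts. Mir17hg had 17 counts (1.71 CPM) in WT, 472 (42.4 CPM) in the Dgcr8 knockout and 509 (41.4 CPM) in the Dicer knockout, 24.8-fold (15.3 to 42.9) and 24.2-fold (14.9 to 41.8) above WT, and the knockouts differed by a ratio of 1.03 (0.903 to 1.17). D7Ertd143e, the noncoding transcript that overlaps the miR-290 to miR-295 cluster, had 50.4 CPM in WT, 433 CPM in the Dgcr8 knockout and 91.3 CPM in the Dicer knockout, 8.59-fold (7.83 to 9.44) and 1.81-fold (1.63 to 2.02) above WT. Hosts at least 2-fold higher than WT in the Dgcr8 knockout and at least 2-fold lower in the Dicer knockout were Mirg (20, 173 and 0 counts in WT, Dgcr8 and Dicer knockout), Meg3 (101, 242 and 6) and Rian (413, 1287 and 34). Mir22hg (26, 55 and 15), A930011O12Rik (152, 279 and 112) and E130102H24Rik (12, 30 and 10) were within 2-fold of WT on the log2(CPM + 1) scale in both knockouts, and their log2 ratios between the knockouts were 1.42, 1.37 and 1.03. The counting interval of E130102H24Rik in the Dicer knockout against WT, 0.260 to 1.70, included no difference. Dleu2, which holds miR-15a and miR-16-1, had 2, 22 and 4 counts, C430049B03Rik, next to miR-322 and miR-503, 2, 19 and 6, and 6430411K18Rik 0, 24 and 2; the last lies opposite the protein-coding gene Rtl1, and strand use in the counting is not given in the sources used here. Snhg4 was at least 2-fold lower than WT in both knockouts (320, 71 and 132 counts), and 2610203C20Rik (56, 29 and 7) was at -0.88 in the Dgcr8 and -2.08 in the Dicer knockout. Snhg10 (15, 5 and 7), 2900076A07Rik (20, 11 and 12), Ftx (16, 11 and 17), AI854517 (12, 13 and 13) and Gm20748 (68, 45 and 89) differed by less than 2-fold on the log2(CPM + 1) scale in each pair. D7Ertd715e, which is a member of the list of noncoding hosts but has no miRNA gene in its span or within 2 kb, had 159 counts in WT, 168 in the Dgcr8 knockout and 464 in the Dicer knockout, a log2 ratio of -1.26 between the knockouts. Of 5 noncoding hosts whose miRNA genes have no listed mature miRNA, 2810008D09Rik (340, 114 and 140 counts) was at least 2-fold lower than WT in both knockouts and 5330426P16Rik (23, 10 and 7) in the Dicer knockout, while Sox2ot (4, 5 and 21), 5730408K05Rik (23, 48 and 60) and Raver1-fdx1l (852, 1172 and 1045) were within 2-fold of WT on the log2(CPM + 1) scale. Against WT the list of noncoding hosts had a median of 0.72 in the Dgcr8 knockout (percentile 97.87, or 96.16 with a floor of 5 CPM). In the Dicer knockout it was -0.69 (percentile 1.54, or 11.49 without a floor). The 6 members at least 2-fold higher in the Dgcr8 knockout included Mirg, Meg3, Rian and 6430411K18Rik of the Dlk1-Dio3 locus. The 4 at least 2-fold lower in the Dicer knockout included Mirg, Meg3 and Rian. Transcripts of 1 locus are not independent, so these medians do not describe miRNA hosts in general. Protein-coding hosts had medians of 0.38 (percentile 98.44; 96.17 with a floor of 5 CPM) and 0.27 (percentile 93.32), with 2010111I01Rik at 2.86 and 2.16 and Ctdsp1 at 1.80 and 1.92.

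**Figure D4:**
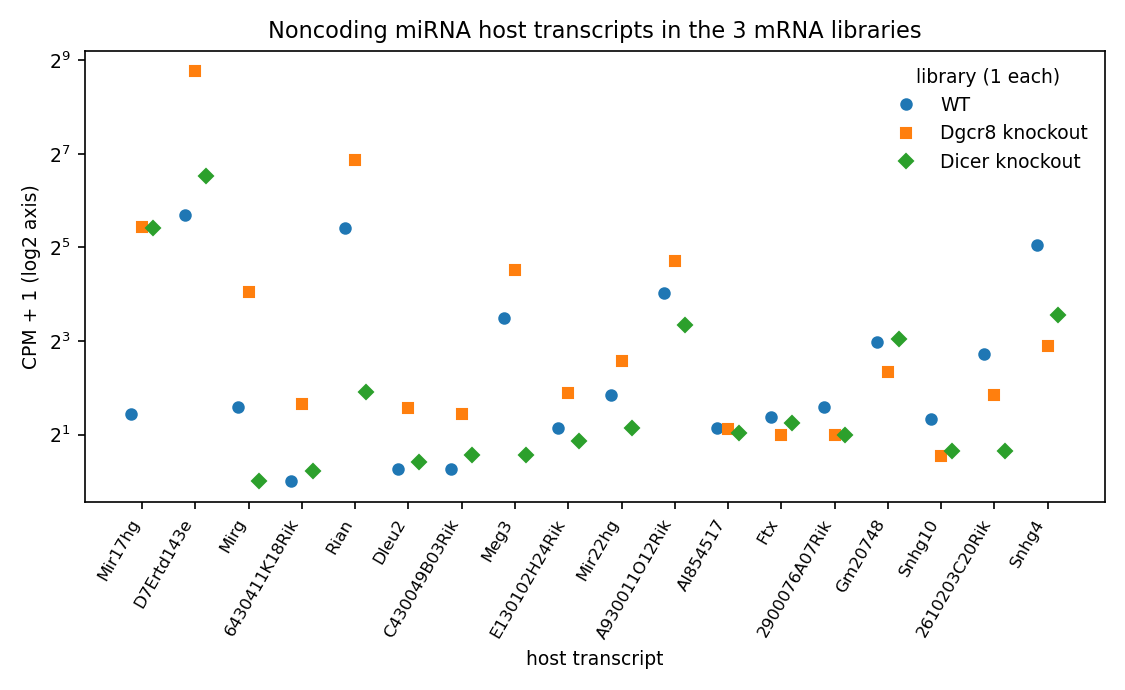
CPM + 1 on a log2 axis of the 18 noncoding miRNA host transcripts that pass the floor and have a listed mature miRNA, in WT (circles), Dgcr8 knockout (squares) and Dicer knockout (diamonds), 1 library each. Mir17hg lies at 42.4 and 41.4 CPM in the knockouts and D7Ertd143e at 433 and 91.3 CPM.

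In the WT small RNA library, 1 cluster made up most of the miRNA reads. The miR-290 to miR-295 cluster, specific to early embryonic cells, took 78.1% of the reads (exact Clopper-Pearson 95% interval 78.0 to 78.1). MiR-293-3p alone took 38.5% (38.4 to 38.5), followed by miR-294-3p with 10.2%, miR-291a-3p with 9.16%, miR-292-3p with 7.64%, miR-295-3p with 6.31% and miR-293-5p with 3.97%. The next were miR-96-5p with 3.55%, miR-182-5p with 2.47%, miR-292-5p with 1.83% and miR-25-3p with 1.01%, and these 10 miRNAs made up 84.7%. Lower members of the miR-290 to miR-295 cluster were miR-291b-3p (4322 reads), miR-291a-5p (3867), miR-291b-5p (2290), miR-290-5p (1041), miR-290-3p (447), miR-294-5p (216) and miR-295-5p (78). The cluster of miR-182, miR-183 and miR-96 took 6.22% and the other abundant stem cell miRNAs 3.35%. The miR-106b-25 cluster took 1.87% (1.85 to 1.88), with 26234 reads of miR-25-3p, 12433 of miR-93-5p, 8793 of miR-106b-5p, 859 of miR-106b-3p, 68 of miR-25-5p and 12 of miR-93-3p. The Dlk1-Dio3 locus took 0.892%, the miR-106a-363 cluster 0.879% (0.868 to 0.891), the Sfmbt2 intron cluster 0.527%, the miR-15/16 family 0.380%, the family of miR-130 and miR-301 0.309% and the differentiation miRNAs 0.198%. The let-7 family took 0.0335% (0.0313 to 0.0358). Splitting multi-locus miRNAs evenly over their loci gave 0.305% for the Sfmbt2 intron cluster and 0.239% for the miR-15/16 family. It gave 0.135% for the differentiation miRNAs and 0.0244% for let-7. The family of miR-130 and miR-301 stayed at 0.309%, so the order of these shares depends on this choice. The miR-302 to miR-367 cluster took 0.0117% (0.0104 to 0.0131), with 122 reads of miR-302b-3p, 108 of miR-302d-3p, 36 of miR-367-3p, 17 of miR-302a-3p, 13 of miR-302c-3p, 7 of miR-302a-5p and 1 of miR-302b-5p.

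The miR-17~92 cluster took 0.326% of the reads (0.319 to 0.333), and its 6 members, which come from 1 primary transcript, were far apart. With both arms added, miR-17 had 3157 reads, miR-19b 2555, miR-20a 1727, miR-18a 541, miR-19a 273 and miR-92a 208. Relative to miR-17, miR-19b was at 0.809 (0.768 to 0.853), miR-20a at 0.547 (0.516 to 0.580), miR-18a at 0.171 (0.156 to 0.188), miR-19a at 0.0865 (0.0761 to 0.0979) and miR-92a at 0.0659 (0.0570 to 0.0758), so the highest member was 15.2 times the lowest. MiR-17 was the highest only with its arms added: over the more abundant arm of each member, miR-19b was at 1.53 and miR-20a at 1.04 relative to miR-17, and the highest was 15.8 times the lowest. MiR-17 had 1497 reads of the 5p arm and 1660 of the 3p arm, while miR-20a had 1721 and 6, and miR-18a 535 and 6. MiR-19a had 192 reads of the 3p arm and 81 of the 5p arm. MiR-19b and miR-92a are also made by the miR-106a-363 cluster, and without them the highest was 11.6 times the lowest. Reads of small RNAs depend on adapter ligation, so ratios between miRNAs of 1 library are not ratios of molecules.

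The last comparison set primary transcripts beside mature miRNAs over 60 host loci. The level of the host in the Dgcr8 knockout had a Pearson r of 0.21 and a Spearman rho of 0.09 with the mature level in WT on log2 scales, across loci that are not independent replicates. With the WT host level the values were -0.02 and -0.08, and with the Dicer knockout level 0.09 and 0.01. Over the 18 noncoding hosts, a choice made after the data were seen, r was 0.49 and rho 0.35. These include D7Ertd143e, and no value without it was computed for them. Over all host loci, r was 0.13 without the miR-290 to miR-295 cluster. D7Ertd143e had the highest mature level, 2026525 reads. Mir17hg, at 42.4 CPM in the Dgcr8 knockout, stood beside 8461 mature reads, and Mir22hg, at 4.94 CPM, beside 17917. The protein-coding gene Mcm7, host of miR-106b-25, had 792 CPM in the Dgcr8 knockout beside 48399 mature reads. CPM values are not divided by transcript length, so levels of different hosts are not on a common molar scale.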

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

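At 5 CPM or more in the higher knockout library, 14 genes were at least 2-fold from WT in opposite directions in the knockouts; the difference was not tested, since each group has 1 library, and these genes were chosen by their values. Simulated unchanged libraries gave 0 such genes, with no floor of 5 CPM, at an assumed coefficient of variation of 0.2 and 23.45 at 0.4. Higher than WT in the Dgcr8 knockout and lower in the Dicer knockout were 9 genes, here with the log2 ratio of the Dgcr8 to the Dicer knockout. The noncoding transcripts of the Dlk1-Dio3 locus were Rian (4.96), Mirg (4.05) and Meg3 (3.94). The others were Kbtbd11 (4.58), the ferlin gene Myof (4.08), the testis ribosomal protein gene Rpl10l (2.69), the adenylate kinase gene Ak7 (2.6), the receptor gene Notch4 (2.53) and the sarcomere gene Mypn (2.48). Lower in the Dgcr8 knockout and higher in the Dicer knockout were 5 genes: the germ cell and naive pluripotency gene Dppa3 (-3.61), the exon junction gene Magohb (-2.94), Pgap1 (-2.49), Ccdc91 (-2.15) and the ubiquitin ligase adaptor gene Klhl13 (-2.08). Dppa3 had 49 counts in WT, 11 in the Dgcr8 knockout and 287 in the Dicer knockout.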

How the results depend on the processing

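No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. The 1-row-per-copy, ribosomal protein, chromosome, noncoding-host and span alternatives were chosen after seeing the data; the others were planned. No called value changed sign. Summing rows with the same symbol merged 2 rows and is nearly void. Counts of genes are given as higher and lower, and the cause of each shift was not tested beyond the rule that defines it. A pseudocount of 0.1 gave 849 and 1004 genes between the knockouts and a covariance of 1.29 between the ratios to WT. A pseudocount of 5, which shrinks low genes, gave 1087 and 411 for Dgcr8 against WT, 1232 and 591 for Dicer against WT, 182 and 222 between the knockouts, 706 and 287 in both, and a covariance of 0.385. A floor of 5 CPM, with fewer genes tested, gave 696 genes lower for Dgcr8 against WT and 415 lower between the knockouts. In the same order of comparisons, the 4-fold rule gave 342 and 159, 539 and 233, 63 and 114, and 242 and 102 in both; the 1.5-fold rule gave 3581 and 2345, 3759 and 2642, 1642 and 1618, and 2537 and 1683. The lists with a low median in Dicer against WT were 4, and 2 with a pseudocount of 5, 2 without a floor and 2 with a floor of 5. The miR-17~92 share was 0.530% without the most abundant miRNA, 0.282% with main arms only and 0.274% when multi-locus miRNAs were split; the miR-290 to miR-295 share was 64.4% and 77.4% under the first 2 of these. For hosts against mature miRNAs, Spearman rho was 0.140 without a floor; Pearson and Spearman values were -0.024 and -0.0838 with the WT host level, 0.0894 and 0.0098 with the Dicer knockout level, and 0.491 and 0.347 over noncoding hosts; Pearson r was 0.128 without the miR-290 to miR-295 cluster. Under these settings 15 values of list medians moved inside the random range and 470 kept their side of its limits. Of these, 19 changed sign, each of a list inside the random range in the report, such as mesoderm without a floor (0.09 in Dicer against WT and -0.11 between the knockouts) and trophectoderm with a floor of 5 (0.05 between the knockouts). The size of a median depended on the pseudocount even where its side did not. With 0.1 and 5, noncoding hosts between the knockouts had medians of 1.94 and 0.47. For 2-cell-like genes in Dicer against WT these were 4.09 and 1.59, and for germline genes in Dgcr8 against WT -1.33 and -0.33. Depth limits genes below about 10 counts, where 1 CPM is 9.93 counts in WT.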

Other observations

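All tests below on the WT library, the reported miRNA targets, Mir17hg, the noncoding hosts and the distal part of chromosome 1 were chosen after their results were seen; the others were chosen before. Genes named in the next sentences were also chosen after their values were seen. Several HoxA genes, which pattern the body axis, were high in the Dgcr8 knockout. Hoxa3 had 3 counts in WT, 132 in the Dgcr8 knockout and 19 in the Dicer knockout, Hoxa5 had 1, 89 and 27, and Hoxa9 had 0, 185 and 15. Nnt, a mitochondrial transhydrogenase gene, had 145, 790 and 1402 counts. The Y-linked gene Eif2s3y had 14 counts in WT and 0 in both knockouts. Myc was 4.48-fold lower than WT in both knockouts, while its relative Mycn was 3.05-fold and 4.57-fold higher.

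The 1974 genes at least 2-fold from WT in the same direction in both knockouts were set against 4 explanations. Taking off the median of each of 20 bins of genomic span kept 87.7% of them, and leaving the 100 most abundant genes out of the totals kept 94.5%, which argues against span bias or a few abundant genes as the whole cause. The reported AAGUGC-seed and miR-17~92 targets lay at the percentile 100 in both, as loss of the miRNAs that target them would give. With them, 10 of the 24 lists had a high median in each pair. Some of these share members with the targets, such as E2f1 in the G1/S list and Lats2 in the TGF-beta list, and are not independent of them. Neural ectoderm genes, none of which is on the target list, were also high in both (percentiles 99.83 and 99.88), so a high median is not specific to the targets. A WT culture that stands apart would give the same covariance (0.735) as effects shared by the knockouts, and with 1 WT library these cannot be told apart.

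Genes of chromosomes 8 and 1 were higher in the Dgcr8 than in the Dicer knockout, with medians of 0.48 over 591 genes and 0.30 over 566, where the other autosomes lay between -0.12 and 0.06. Against WT, of the medians of these chromosomes, that of chromosome 8 in the Dicer knockout (-0.29) lay outside the range of the other autosomes (-0.09 to 0.35), while that of chromosome 8 in the Dgcr8 knockout (0.19, range -0.05 to 0.42) lay inside. The median of chromosome 1 hides opposite shifts in the Dgcr8 knockout, from -0.43 to -0.15 in the first 4 of 10 equal parts and from 0.34 to 0.61 in the last 5. In the Dicer knockout these parts had medians from -0.37 to -0.01 and from -0.11 to 0.04, so medians below 0 in the first 4 were found in both knockouts. On chromosome 8, 86.5% of the genes were above the median of all genes. Chromosomes 8 and 1 were singled out by their medians, which a few genes cannot move, so such shares do not test a few strongly different genes. The smallest shift of chromosome 8 over 3 expression tertiles was 0.489, which argues against expression level as the cause. Its proximal and distal parts were both shifted, by at least 0.428, as a different number of copies would give. On chromosome 1, 68.7% were above the median and the smallest tertile shift was 0.246, but the smaller shift of its proximal and distal parts was 0.0613 and the larger 0.495, against a whole extra copy, while 85.5% of the distal genes lay above the median. A different number of copies of chromosome 8 and of distal chromosome 1 in the cultures may explain this (3 copies against 2 would give 0.58); DNA was not measured here, and culture and genotype are confounded.

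Mir17hg was near the same level in both knockouts, while the hosts of the Dlk1-Dio3 locus were higher in the Dgcr8 than in the Dicer knockout and those elsewhere went both ways. The 16 noncoding hosts outside Dlk1-Dio3 with a miRNA gene had a median log2 ratio of 0.19 between the knockouts, 10 above 0, at the percentile 87.16 of matched lists, which leaves open whether primary transcripts are kept uncut where Microprocessor is lost. The answer depends on the hosts taken: the 12 with a listed mature miRNA had a median of 0.95, 9 above 0 (percentile 100), and of the 4 without one, 1 was above 0. The floor of 1 CPM fixed some of these signs. Dleu2, C430049B03Rik, E130102H24Rik and 2610203C20Rik reached it in the Dgcr8 but not the Dicer knockout, and Ftx and Sox2ot only in the Dicer knockout. Keeping of uncut primary transcripts where Microprocessor is lost does not cover Mir17hg in the Dicer knockout, where Microprocessor was not the target. Its ratio to WT there was at least 14.9 by its lower bound, which covers counting error only. Higher transcription of the locus there stays open and was not tested.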
